A study of Mus musculus with 6 samples.

How the data were processed

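Bulk RNA-seq was made from 3 knockout and 3 control samples of mouse liver. Per the labels' protocols, RNA was extracted with TRIzol, mRNA was enriched on oligo(dT) beads and fragmented, and cDNA was primed with random hexamers and amplified by PCR. Per the submitters' processing notes, the tools were HISAT2, Bowtie2 and RSEM 1.3.1 and the genome build was GRCm38; the order of the steps, trimming and the strand setting are not given in the sources used here. The table of the whole series holds, per gene and library, estimated counts, FPKM and TPM that the authors computed, per the file headers. It also holds the authors' means per group and their own DESeq2 comparison, with a log2 fold change, a p-value and a q-value per gene, per the file headers. Columns were matched to samples by the group and number in the column names, which call the controls wild type, whereas the labels give a floxed genotype. All 16140 genes in the table are typed as mRNA, and it holds no mitochondrially encoded genes, so a fixed list of these had no members to test.

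Estimated counts, which the authors deposited with about 5% of values not whole (4.70% to 5.12% per library differ at all from the nearest whole number, and 4.50% to 4.91% by over 0.01), were rounded to whole numbers. Totals per library were 15550289 to 18680195. At these depths a count of 0 allows up to 3 counts, or 0.155 to 0.201 CPM per library. PCR reads without molecular identifiers are not independent molecules, so counting intervals and floors cover counting error only. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 18.9), so all 6 were kept as separate samples.

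Genes with low counts were removed with edgeR's filterByExpr, which left 12173 genes, and libraries were scaled with TMM factors. Knockout and control were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Standard errors were derived from the F statistic. Values per gene are CPM scaled by the TMM factors. For genes with 1 to 7 knockout counts the ratio of summed counts is given with an exact 95% interval, and for genes with none a bound against a floor of 3 counts over the group. A simulation with the real means, library sizes and dispersions and 200 changed genes recovered 59.8% of genes with a log2 change of 1 and 99.1% of those with a log2 change of 2, among 12075 genes tested; 5.33% of calls were false.

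Gene lists of liver pathways, liver zones and other cell types were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Of 56 lists, 49 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The lists too small to test, of neutrophil, pancreas, adipocyte, muscle, gallbladder and gut markers and of Y-linked genes, held 1 called gene, the neutrophil and acute phase gene Lcn2; adjusted over the list alone, 1 neutrophil and 3 of 4 adipocyte markers were lower. The named genes were Selenoo and, in each direction, the 12 genes with the smallest p among those with an adjusted p under 0.05, a mean log2 CPM of at least 0 and groups that did not overlap, leaving out predicted gene models; each list added its members with the smallest p. The rule left out 21 called models, 3 higher and 18 lower.

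Alternatives were DESeq2 size factors, upper-quartile scaling, no low-count filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with a trend, a minimum 2-fold change, an adjusted p of 0.1, and, for lists, an estimated correlation, fry and ranks. Removal of each library's trend on transcript length and GC content, and DESeq2 on the genes kept by filterByExpr without its independent filtering, were chosen after seeing the data. Lengths and GC came from GENCODE's longest protein-coding transcript per symbol on GRCm38 and were found for 98.1% of tested genes.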

Results

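Livers of mice with a liver-specific knockout of Selenoo, the gene of the mitochondrial selenoprotein SelO, were compared with livers of floxed mice that kept the gene, all on a normal diet. The knockouts carried floxed alleles with hepatocyte Cre, and the controls floxed alleles without Cre. An effect of Cre therefore cannot be told apart from loss of Selenoo. Poly(A)-selected RNA of 3 knockout and 3 control livers was sequenced in bulk. Gene-level estimated counts summed to between 15550289 and 18680195 per library, and 12173 of the 16140 genes in the table had enough counts to be tested. The question was how loss of SelO in the liver changes the liver transcriptome. The labels do not say in words that each library came from a different mouse, so p-values measure the spread between these samples.

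Selenoo (NCBI Gene 223776, chromosome 15, 89089038 to 89100339 on the plus strand of GRCm38) was reduced in all 3 knockout libraries. Its counts were 1413, 1630 and 1852 in the controls and 117, 163 and 135 in the knockouts. In CPM, counts scaled to library size, the means were 91.7 ± 6.50 (SD, n = 3) in control and 7.76 ± 1.52 (SD, n = 3) in knockout livers, so that 8.46% ± 1.65 (SD, n = 3) of the control level was left, with single libraries between 6.86% and 10.2%. The log2 fold change was -3.56 ± 0.17 (SE), with an adjusted p of 4.64e-05 in edgeR's quasi-likelihood test. In the authors' deposited table the log2 fold change of Selenoo was -3.56. The counts cover the whole gene, so they do not show which exons the remaining reads came from.

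**Figure D1:**
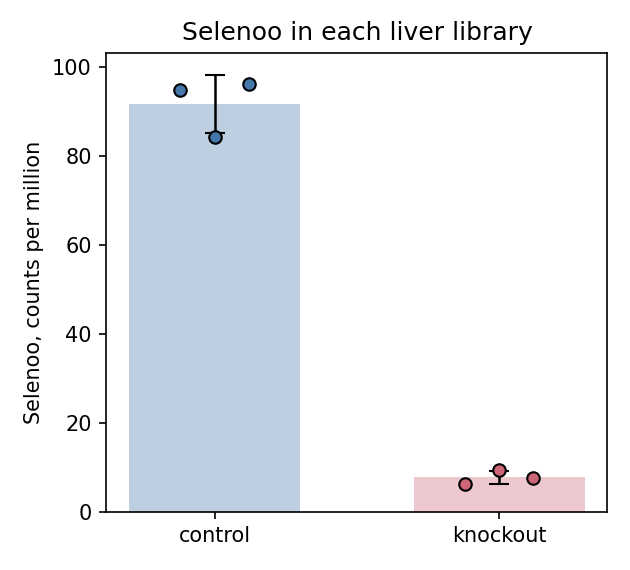
Selenoo in CPM (y axis, from 0) in control and knockout livers; points are single libraries, bars are means and error bars are SD of 3 libraries. Knockout libraries lie between 6.29 and 9.32 CPM and controls between 84.2 and 96.1 CPM.

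The libraries separated by genotype on the first principal component of the 1000 most variable genes, which held 49.3% of the variance. Controls lay between -20.5 and -12.7 on it and knockouts between 16.1 and 19.5. Controls were more spread out than knockouts: log2 CPM correlated across genes with r from 0.9695 to 0.9807 among controls and from 0.9859 to 0.9896 among knockouts. Between the groups r ran from 0.9606 to 0.9776. Control replicate 3 correlated with the knockouts at 0.977, 0.9758 and 0.9776, above its r of 0.9695 with control replicate 1. Control replicate 1 stood apart from the other libraries on the second component (17.1% of the variance), at 19.4. The libraries also differed in how abundance deviated with transcript length: Spearman's rho across genes was -0.30 in control replicate 1, -0.22 in control replicate 2, 0.27 in control replicate 3 and 0.27, 0.085 and 0.088 in the knockouts. Genes are not independent replicates in these correlations.

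**Figure D2:**
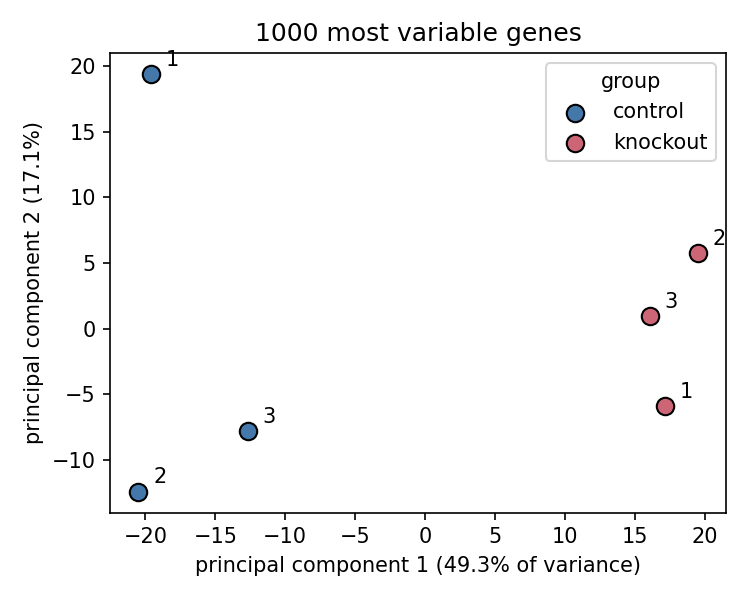
Principal components 1 (x axis) and 2 (y axis) of log2 CPM of the 1000 most variable tested genes; each point is a library, numbered by replicate and coloured by group. Controls lie between -20.5 and -12.7 and knockouts between 16.1 and 19.5 on component 1.

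Between knockout and control livers, 181 of 12173 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 94 of them higher and 87 lower in knockout livers. The median fold was 2.20 among the higher and 2.72 among the lower genes, and 129 genes changed at least 2-fold (59 higher and 70 lower). All 181 had groups that did not overlap, as did 25.2% of all tested genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 2255 of the 12173 genes, and unadjusted counts of list members are to be read against that share. The authors' deposited table lists 560 genes with a q value under 0.05 (327 higher and 233 lower), and it holds 180 of these 181 genes, each in the same direction. The number of calls depended on single libraries: it was 361 without control replicate 1, 77 without control replicate 2, 668 without control replicate 3, and 59, 43 and 60 without knockout replicates 1, 2 and 3. On log2(FPKM + 0.1) values with limma the split was 52 higher and 74 lower.

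**Figure D3:**
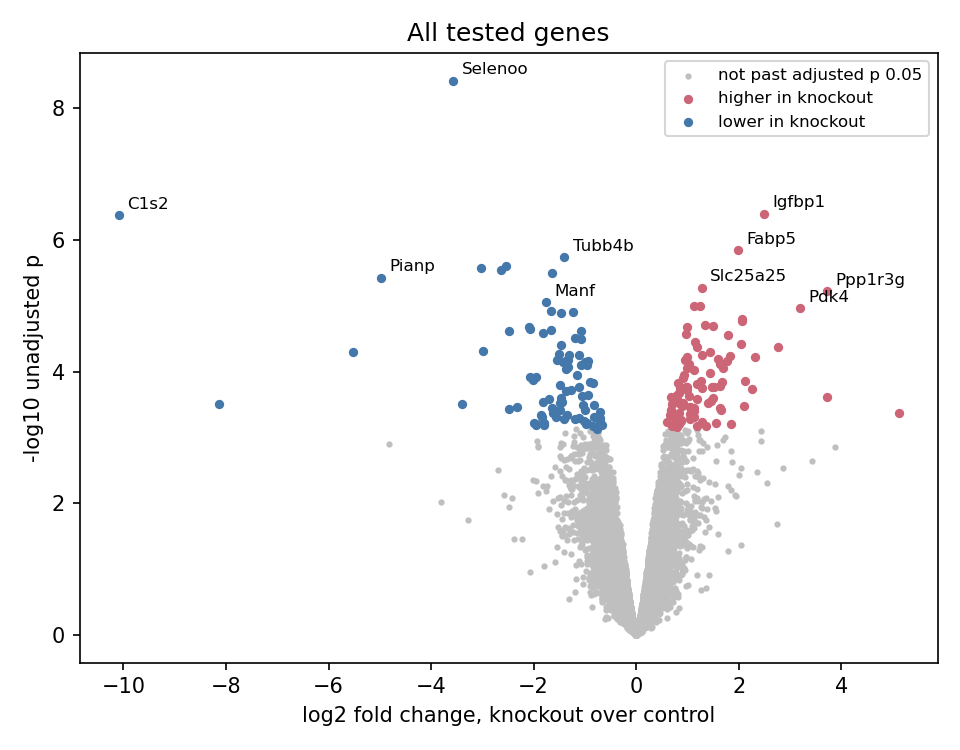
Log2 fold change of knockout over control (x axis) against -log10 of the unadjusted p of edgeR's quasi-likelihood test (y axis) for the 12173 tested genes; 94 coloured points are higher and 87 lower in knockout livers at an adjusted p under 0.05. The position of C1s2 and of other genes with almost no knockout counts depends on the prior count and is not a measured fold.

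The 12 higher genes with the smallest p included secreted, metabolic and regulatory genes. Igfbp1, a secreted binding protein for insulin-like growth factors, rose from 45.4 ± 3.45 to 254 ± 68.0 CPM (SD, n = 3), with an adjusted p of 0.0017 in edgeR's test. Fabp5, a fatty acid binding protein, rose from 22.6 ± 4.47 to 88.8 ± 14.0 CPM. Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1, rose by 3.73 ± 0.41 (log2, SE), and Pdk4, the kinase that inhibits pyruvate dehydrogenase, by 3.19 ± 0.38. The mitochondrial carrier Slc25a25 rose by 1.28 ± 0.14, the transcription factor gene Jun by 1.13 ± 0.13 and Ppm1k, a mitochondrial phosphatase of branched-chain amino acid breakdown, by 1.25 ± 0.15. Hunk (2.07 ± 0.26) and Map3k13 (2.05 ± 0.26), both kinases, Clstn3 (1.35 ± 0.17), Spc25 (1.51 ± 0.19), a kinetochore gene, and Cpeb2 (0.99 ± 0.13), an mRNA-binding protein, made up the rest of the 12, with adjusted p of at most 0.0101.

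Among the 12 lower genes with the smallest p, the tubulin gene Tubb4b fell from 127 ± 10.6 to 48.1 ± 3.93 CPM (SD, n = 3), Tuba4a from 169 ± 19.6 to 72.4 ± 7.29 and Tuba1c from 88.8 ± 17.3 to 32.2 ± 4.31. Serpina3c (-2.55 ± 0.25, log2 and SE), Serpina3i (-3.03 ± 0.30) and Serpina11 (-1.08 ± 0.14) also fell. Of 31 serpin genes tested, counted after the data were seen, 3 were higher and 3 lower past the threshold, and 22 had a negative fold change; DESeq2 called 3 higher and 7 lower. Without control replicate 1 these were 3 and 6, without control replicate 2 they were 2 and 3, and without knockout replicates 1, 2 and 3 they were 1 and 3, 0 and 2, and 0 and 3. Serpina and tubulin genes belong to families of similar sequence, and the counting may divide reads among members. Manf, which the endoplasmic reticulum makes under stress, was lower too (-1.76 ± 0.20), as were the B cell chemokine Cxcl13 (-1.66 ± 0.20), the acute phase gene Lcn2 (-2.09 ± 0.27) and Pik3c3, a lipid kinase of autophagy (-2.08 ± 0.27). The adjusted p of these genes in edgeR's test was at most 0.0101. Without knockout replicate 2 it was 0.0507 for Tuba4a and 0.0711 for Serpina11, and without knockout replicate 1 it was 0.0536 for Pik3c3.

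A pair of lower genes lay close together on chromosome 6 and had almost no counts in knockout livers. C1s2 (124624625 to 124636085, GRCm38), a copy of the complement protease gene C1s, had 1174, 910 and 373 counts in the controls and 1, 0 and 1 in the knockouts, a ratio of 1230 with a 95% exact counting interval of 341 to 10200. Pianp (124996720 to 125003096) had 71, 112 and 45 counts against 3, 3 and 1, a ratio of 32.7 with an interval of 15.6 to 82.2. These intervals cover counting error only, and C1s2 may share reads with C1s1.

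In the fixed list of gluconeogenesis and glycogen genes, 17 of 25 had a positive and 8 a negative fold change. Of the 25, 6 rose over all genes tested, none fell, and 9 rose adjusted over the list alone. The 6 included Ppp1r3g, Ppargc1a (1.18 ± 0.16), a coactivator of the fasting response, and G6pc (0.91 ± 0.15) and Pck1 (0.76 ± 0.15). G6pc and Pck1 encode the committed enzymes of glucose output. The others were Igfbp1, a secreted binding protein, and Tat (1.48 ± 0.25), which is also on the amino acid list. The camera adjusted p was 0.000316, and the adjusted p = 0.577 with an estimated correlation. The list's median log2 fold change was 0.131, and 0.226, 0.448 and 0.239 without control replicates 1 and 3 and knockout replicate 1. Of 47 genes of fatty acid oxidation and PPAR-alpha targets, 3 rose (Pdk4, Ehhadh at 1.52 ± 0.25 and Acot1 at 1.36 ± 0.27), with 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.05e-07, adjusted p = 0.577 with an estimated correlation). Their median of 0.326 was 0.202 without control replicate 2.

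Genes of the unfolded protein response were lower, with 8 of 24 past the threshold, none higher, and 15 lower adjusted over the list alone. They included Hspa5 (-1.11 ± 0.18), the main chaperone of the endoplasmic reticulum, Xbp1 (-0.95 ± 0.14) and Hyou1 (-1.40 ± 0.27). The camera adjusted p was 2.72e-07, and the adjusted p = 0.577 with an estimated correlation. Of 17 heat shock genes 1 fell, Hsph1 (-0.84 ± 0.17), with 7 lower adjusted over the list alone (camera adjusted p = 0.00141, adjusted p = 0.577 with an estimated correlation).

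Several lists of immune genes were lower in camera with its preset correlation, and none with an estimated one. Of 8 genes of antigen presentation by MHC class II, 4 fell and all 8 were lower adjusted over the list alone, among them H2-Aa (-1.63 ± 0.31) and Cd74 (-1.57 ± 0.30). The camera adjusted p was 4.00e-07, and the adjusted p = 0.577 with an estimated correlation. None of 12 T and NK cell markers passed over all genes, while 9 were lower adjusted over the list alone (camera adjusted p = 2.04e-07, adjusted p = 0.577 with an estimated correlation). None of 33 interferon response genes passed, while 14 were lower adjusted over the list alone (camera adjusted p = 4.87e-08, adjusted p = 0.61 with an estimated correlation). The interferon list's median was -0.50 in control replicate 1, measured from the control mean, against -0.46, -0.66 and -0.64 in the knockouts, so the groups overlapped, and the median log2 fold change of -0.677 was -0.4 without control replicate 2. Inflammatory cytokines and chemokines (1 of 17 lower, Cxcl13, and 3 adjusted over the list alone; camera adjusted p = 0.00322, adjusted p = 0.577 with an estimated correlation) and B and plasma cell markers (1 of 6 lower, Jchain, also 1 adjusted over the list alone; camera adjusted p = 0.0198, adjusted p = 0.681 with an estimated correlation) were lower too. Of 16 Kupffer cell markers none passed and 2 were lower adjusted over the list alone (camera adjusted p = 0.00947, adjusted p = 0.681 with an estimated correlation). The Kupffer call was lost without control replicate 2 (adjusted p = 0.0623), control replicate 3 (0.28) or knockout replicate 3 (0.0737), and the B cell call without control replicate 2 (0.122), where the median went from -0.644 to -0.257. The groups overlapped in both lists: control replicate 1 was at -0.49 against -0.44, -0.22 and -0.97 in the knockouts for B cells, and at -0.31 against -0.23, -0.22 and -0.44 for Kupffer cells. Of 10 markers of monocyte-derived macrophages none passed in either way (camera adjusted p = 0.00816, adjusted p = 0.577 with an estimated correlation). Their median of -0.496 was -0.319 without control replicate 2, and the call was lost with the filter of 1 CPM in 3 libraries (adjusted p = 0.172). At an unadjusted p under 0.05 in edgeR 9 T and NK cell, 21 interferon, 7 Kupffer and 5 monocyte-derived macrophage genes passed, and DESeq2 called 4, 9, 2 and 0 of them. Over all tested genes, 2255 of 12173 passed unadjusted. Of 4 tested adipocyte markers, too few for camera, none passed over all genes and 3 were lower adjusted over the list alone (median of -0.641).

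Among sex-dependent and secreted liver genes, 1 of 23 male-biased genes rose, Serpina1e (1.67 ± 0.27), with 14 higher adjusted over the list alone (camera adjusted p = 2.05e-07, adjusted p = 0.577 with an estimated correlation). Their median of 0.733 was 0.422 without control replicate 3. Female-biased genes did not pass (0 of 13, 5 at an unadjusted p under 0.05, 1 with DESeq2; camera adjusted p = 0.563), and their median of -0.308 was 0.244 without control replicate 3; without control replicate 2 it was -0.625 and the list passed (adjusted p = 0.00651). Of 20 major urinary protein genes, which are nearly identical copies whose reads cannot be assigned with certainty, 3 rose and 11 were higher adjusted over the list alone (camera adjusted p = 6.05e-06, adjusted p = 0.61 with an estimated correlation). The groups of the urinary protein list overlapped, with control replicate 1 at 0.54 and knockout replicate 1 at 0.33, and its median of 1.24 was 0.683 without knockout replicate 2. Y-linked genes had counts in all 6 libraries, and none of the 4 tested passed.

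Other lists passed as well. Periportal hepatocyte genes (3 of 26 higher, 4 adjusted over the list alone; camera adjusted p = 0.00482, adjusted p = 0.577 with an estimated correlation) included Cdh1 at 1.63 ± 0.27. Immediate early genes (2 of 20 higher; 5 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0192, adjusted p = 0.577 with an estimated correlation) included Jun and Btg2. Bile acid genes (0 of 26, 4 higher adjusted over the list alone; camera adjusted p = 0.00816, adjusted p = 0.577 with an estimated correlation) and tricarboxylic acid cycle genes (0 of 23 in either way; camera adjusted p = 0.018, adjusted p = 0.66 with an estimated correlation) had positive medians. Of 36 genes of amino acid catabolism and the urea cycle 1 rose, Tat, and 1 was higher and 1 lower adjusted over the list alone (camera adjusted p = 0.033, adjusted p = 0.681 with an estimated correlation). Cholesterol synthesis genes (2 of 25 lower, Mvd at -1.50 ± 0.21 and Msmo1 at -1.07 ± 0.16; 4 adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.767 with an estimated correlation) had a median of -0.23, which was -0.05 without control replicate 3 (camera adjusted p = 0.76) and -0.12 without knockout replicate 3 (0.0858). The camera call of the tricarboxylic acid cycle was lost without control replicate 2 (adjusted p = 0.0949) or knockout replicate 2 (0.0553), that of immediate early genes without control replicate 3 (0.171) or knockout replicate 2 (0.066) or on ranks (0.0506), and that of amino acid catabolism without control replicate 2 (0.243), knockout replicate 2 (0.0874) or knockout replicate 3 (0.132). The immediate early median of 0.222 was 0.0808 and 0.145 without those libraries. The amino acid median of 0.128 was 0.068 without control replicate 2, 0.243 without knockout replicate 1 and 0.0809 without knockout replicate 3. None of 69 ribosomal protein genes passed in either way (camera adjusted p = 0.00172, adjusted p = 0.772 with an estimated correlation). Their median per library ran from -0.34 to 0.34 among the controls, and the camera adjusted p was 0.736 without control replicate 1. Their median log2 fold change of -0.222 was -0.0507 without that library and -0.382 without control replicate 3. With the length and GC trend removed it was -0.0373 and the call was lost (adjusted p = 0.482). At an unadjusted p under 0.05 in edgeR 11 bile acid, 4 tricarboxylic acid cycle and 1 ribosomal protein genes passed, and DESeq2 called 5, 1 and 0. Over all tested genes, 2255 of 12173 passed unadjusted.

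**Figure D4:**
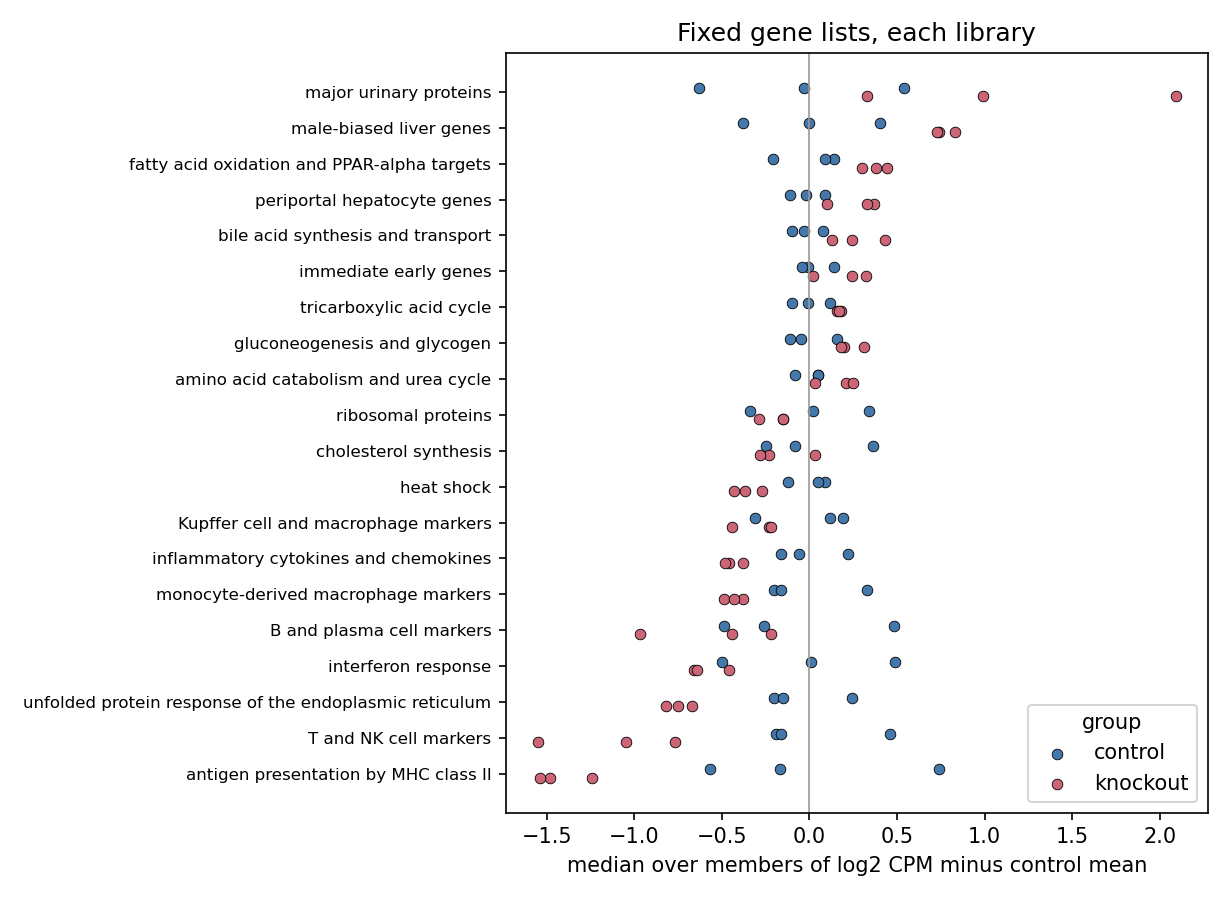
Median over the members of each fixed list of log2 CPM minus the control mean (x axis), for the 20 lists past a camera adjusted p of 0.05 (y axis); each point is a library, coloured by group. For MHC class II the knockouts lie between -1.54 and -1.24 and the controls between -0.57 and 0.74, whereas for ribosomal proteins the groups overlap.

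In all, 20 of 49 tested lists passed camera with its preset correlation of 0.01, 9 higher and 11 lower, and 0 passed with an estimated correlation. The medians per library of knockouts and controls overlapped in 8 of the 20. Other divisions of the same 6 libraries into groups of 3, mixing the genotypes, called up to 18 lists; each of them still holds the genotypes 2 to 1. Of the 63 genes named here and in the closing observations besides Selenoo, 60 were called with all libraries. Of these, 1, 26 and 0 lost their call without control replicates 1, 2 and 3. Without knockout replicates 1, 2 and 3, 28, 34 and 33 lost it. None of the 63 changed sign. In each the groups did not overlap, so leaving out 1 library could hardly change the sign. With the replicate number as a block 24 of the 60 lost their call, with limma on log2(FPKM + 1) 18, on log2(FPKM + 0.1) 12 and with limma-voom 4.

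Selenoproteins other than Selenoo did not move as a list (camera adjusted p = 0.424). Of 19 tested, 1 passed in both ways of adjusting, Dio1, which encodes the deiodinase that activates thyroid hormone and rose from 15.4 ± 6.34 to 77.1 ± 29.6 CPM (SD, n = 3). Genes of selenocysteine synthesis and insertion (0 of 11; camera adjusted p = 0.747), NRF2 targets and glutathione genes (0 of 32; camera adjusted p = 0.532), mitochondrial antioxidant enzymes (0 of 19; camera adjusted p = 0.857), mitochondrial stress genes (0 of 15; camera adjusted p = 0.466) and nuclear-encoded genes of the electron transport chain (0 of 76; camera adjusted p = 0.907) did not pass. Without control replicate 1 the last of these had an adjusted p of 2.89e-05, with a median of 0.18 against -0.07 with all libraries, and with the length and GC trend removed an adjusted p of 0.00476 and a median of 0.0804. At an unadjusted p under 0.05 in edgeR 1, 8, 3, 1 and 4 genes of these 5 lists passed, and DESeq2 called 0, 3, 2, 0 and 0. Over all tested genes, 2255 of 12173 passed unadjusted. Camera tests a shared direction only, and the NRF2 and glutathione list had 15 positive and 17 negative genes. The mixed test of fry allows both directions and does not compare with other genes. Its unadjusted p was 0.0267, 2.25e-06, 0.0743, 0.346 and 0.52 for these 5 lists. Among ATF4 targets 1 of 21 rose, the asparagine synthetase gene Asns (2.77 ± 0.39), and the list did not pass (camera adjusted p = 0.424). De novo lipogenesis (camera adjusted p = 0.122), with Mid1ip1 lower among 26, and the genes around Selenoo (camera adjusted p = 0.439), with Creld2 lower among 25, did not pass either. Markers of stellate cells (0 of 17; camera adjusted p = 0.466), bile duct cells (0 of 8; camera adjusted p = 0.738) and sinusoidal endothelial cells (1 of 19 lower, Lyve1; camera adjusted p = 0.0716) did not pass. Of the stellate and bile duct markers 1 and 0 passed an unadjusted p under 0.05, and DESeq2 called none. Besides the electron transport chain, camera passed 3 of these lists when 1 library was left out: de novo lipogenesis without control replicate 3 (adjusted p = 0.00275), the genes around Selenoo without control replicate 1 (0.0203), and the endothelial list without control replicate 2 (0.034) or knockout replicate 3 (0.015). The endothelial list also passed with the length and GC trend removed (median of -0.138, adjusted p = 0.0221).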

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

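The length and GC correction and the DESeq2 test on the filtered genes were chosen after seeing the data. Selenoo kept its direction and its call in every alternative, with log2 fold changes from -3.714 to -3.43 when 1 library was left out and down to -3.296 in size with limma on log2(FPKM + 1). The 181 calls became 330 without a low-count filter, 513 at the looser adjusted p of 0.1 and 287 with the length and GC trend removed. They became 634 with DESeq2, 636 with DESeq2 on the filtered genes, and 110 with limma on log2(FPKM + 1). The 636 came from the same genes as the 181, so the choice of genes does not account for the rise with DESeq2. Otherwise the cause was not tested. With 1 library left out the calls ranged from 43 to 668, and the cause was not tested. With the replicate number as a block 87 genes were called, 77 of them among the 181. Same-numbered libraries did not deviate together (r of -0.16, -0.079 and -0.076), which gives no sign of pairing. It cannot exclude pairing, since the trend of each library on transcript length also enters these r. The 20 called lists became 0 with an estimated correlation and 2 with fry, neither among the 20 (glycolysis and p53 targets), 17 to 23 with 1 library left out, and 18 with the filter of 1 CPM in 3 libraries, which ended the call of monocyte-derived macrophages (adjusted p = 0.172) and left too few B cell markers to test. Ranks ended that of immediate early genes (0.0506). The first principal component held 44.1% of the variance over all tested genes. No called list changed sign. Some lists not called passed in camera in 1 setting or more: p53 targets without a low-count filter (adjusted p = 0.0402) or control replicate 1 (0.0409), lipid droplet genes without control replicate 1 (0.0453), the cell cycle without control replicate 3 (0.0346), erythroid markers without knockout replicate 1 (0.00971), and those given in the results. Of 3 named genes not called, DESeq2 called 2, C1s1 (0.00616) and Scd1 (0.00733). Among lists not called, medians changed sign as follows, and the cause was not tested. With the length and GC trend removed they were 0.0236 for selenocysteine synthesis, 0.0303 for mitochondrial antioxidant enzymes, 0.0804 for the electron transport chain (camera adjusted p = 0.00476), 0.0261 for glycolysis, 0.106 for the methionine cycle, -0.032 for the clock and -0.0263 for collagen. Upper-quartile scaling gave -0.0172 for the clock and -0.0259 for collagen, no filter -0.0146 for collagen, and the 1 CPM filter -0.0282 for the cell cycle. The replicate block gave 0.00597 for bile duct cells and -0.259 for erythroid markers. With 1 library left out, medians ranged from -0.0919 to 0.0014 for the acute phase, -0.199 to 0.139 for bile duct cells, -0.0764 to 0.299 for the cell cycle, -0.108 to 0.235 for the clock, -0.0909 to 0.167 for collagen, -0.229 to 0.176 for the electron transport chain, -1.13 to 0.692 for erythroid markers, -0.642 to 0.244 for female-biased genes, -0.105 to 0.0199 for glycolysis, -0.0718 to 0.0617 for the methionine cycle, -0.106 to 0.0583 for mitochondrial antioxidant enzymes, -0.187 to 0.00512 for pericentral genes and -0.00729 to 0.177 for stellate cells. Removing the length and GC trend ended the call of ribosomal proteins, whose median went from -0.222 to -0.0373 (camera adjusted p = 0.482). With 3 libraries per group, log2 changes near 1 are often missed.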

Other observations

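The gene sets, windows, panels and tests in this part were chosen after the data were seen, except the leukocyte panel, which was fixed before its values were computed. Of 11 tested tubulin genes, counted because several had been seen among the calls, 5 were lower past the threshold and none higher. All 11 had a negative fold change, also under each other scaling and filter. Those settings could hardly change a sign: they shifted fold changes by a median of -0.0412 to 0.0073, and the tubulin nearest to 0, Tubd1, was at -0.116. The count past the threshold was 6 without control replicate 1 and 3 without control replicate 2, and 3, 2 and 3 without knockout replicates 1, 2 and 3. It was 3 with the replicate number as a block and 6 with DESeq2. Besides the 3 already named, Tubb5 fell from 87.1 ± 14.9 to 43.5 ± 1.08 CPM and Tubb2a from 69.4 ± 15.4 to 33.6 ± 5.71 CPM (SD, n = 3). Their adjusted p in edgeR's test was 0.0153 and 0.0333. Among single genes of ribosome assembly, Ppan, Gnl3, Nop58, Utp14a and Nufip1 had log2 fold changes of -1.06 ± 0.18, -0.77 ± 0.15, -0.70 ± 0.14, -0.70 ± 0.14 and -0.81 ± 0.15 (SE). They were picked from the calls, so they do not show how such genes behaved as a group. Of 2608 pathway and process annotations in the deposited table with 10 to 200 tested genes, 96 passed camera, 31 higher and 65 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.956 with an estimated correlation). The KEGG set of ribosome biogenesis was lower (3 of 71 genes past the threshold, all lower, median of -0.185, camera adjusted p = 0.0247, adjusted p = 0.956 with an estimated correlation). So was the GO set of rRNA processing (2 of 148 lower, median of -0.175, camera adjusted p = 0.00218, adjusted p = 0.956 with an estimated correlation). The GO set of ribosome biogenesis did not pass (2 of 107 lower, median of -0.0968, camera adjusted p = 0.0724).

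The number of calls was set against all 10 divisions of the 6 libraries into groups of 3. The genotypes gave 181 genes and the highest of the others 0 in edgeR, in 1 of 10 divisions; at an unadjusted p under 0.05 they gave 2255 and 811. For gene lists the genotypes gave 20 and the highest of the others 18, again 1 of 10 as many. With 10 divisions a share under 0.05 cannot be reached, and each other division still holds the genotypes 2 to 1.

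Several lists of immune genes were lower in camera with its preset correlation, and none with an estimated one (adjusted p of 0.577 to 0.681). Past the threshold for single genes were 4 of 8 MHC class II genes and 0 of 12 T and NK cell markers in edgeR, where 9 of the latter passed unadjusted and DESeq2 called 4. Control replicate 2 alone is argued against for these 2 lists: without it their medians went from -1.51 to -1.05 and from -1.26 to -0.888, and both other controls lay above all knockouts. It stays open for interferon response genes and B and Kupffer cell markers, whose medians went from -0.677, -0.644 and -0.335 to -0.4, -0.257 and -0.225 without it, with overlapping groups. A lower share of every cell type other than hepatocytes is argued against by the stellate, sinusoidal endothelial and bile duct lists, whose median log2 fold changes were 0.119 (-0.00729 without knockout replicate 3), -0.0946 and -0.057, against -1.26 for T and NK cells. Of 19 endothelial markers 15 were negative, so a smaller share of endothelial cells stays open. A lower share of leukocytes is a candidate explanation: a panel of 16 pan-leukocyte genes had a median of -0.627 and all 16 were negative. Of these 16, 10 had groups that did not overlap, as did 25.2% of all tested genes. None passed an adjusted p of 0.05 in edgeR (11 passed unadjusted, and DESeq2 called 5). The panel's values ran from -0.88 ± 0.20 (Cd52, SE) to -0.09 ± 0.16 (Lcp1, SE). Medians were -1.26 for T and NK cell markers and -0.335 for Kupffer cell markers, so an equal fall in all leukocytes does not by itself describe them. Whether fewer cells were present or each cell had less of these RNAs, and whether genotype or the tissue piece set it, was not tested.

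Clstn3, C1rb, C1s2, Pianp and Chd4 were called among 39 tested genes within 1 Mb of chromosome 6, from 124430756. C1rb, C1s2 and Pianp were lower, while Clstn3 (1.35 ± 0.17) and Chd4 (0.66 ± 0.13, log2 and SE) were higher. No tested gene between C1s2 and Pianp was called. Of 10000 random placements of the calls, a share of 0.025 gave a window as full anywhere (permutation p). C1rb and C1s2 are neighbouring members of a family, and counted as 1 gene they leave 4 in the window and a share of 0.213. Chance placement could thus account for the number of calls. The placements counted calls only and ignored the size of each change. They cannot decide whether the near absence of C1s2, C1rb and Pianp counts in knockouts fell together by chance. The fullest window, with 6, held the Serpina cluster on chromosome 12. C1rb had 54, 29 and 17 control counts and 0 in each knockout, at least 33.4-fold lower against a floor of 3 counts over the group. Shared reads stay open for C1s2 and C1rb. Together C1s1 and C1ra gained 4.79 times the CPM these lost. By pair, C1s1 gained 106 CPM where C1s2 lost 48.3, and C1ra gained 134 where C1rb lost 2. Neither C1s1 nor C1ra passed the threshold in edgeR. DESeq2 called C1s1 (adjusted p = 0.00616, and 0.00616 to 0.321 over the alternatives) but not C1ra. For Clstn3, Pianp and Chd4 shared reads were not tested. Whether strain or litter differed with genotype in this segment was not tested either, for want of reads or genotypes.

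Igfbp1, Pdk4, Pck1, G6pc and Ppargc1a were higher and Angptl8 (-1.82 ± 0.24) and Mid1ip1 lower in knockout livers, a set that feeding state could move. A panel of 10 lipogenic genes, which fasting lowers, had a median log2 fold change of 0.0794. Of these, 8 were positive, but Acss2, Acly, Srebf1, Acaca and Pnpla3 by less than their SE, so the signs do not argue against fasting. The highest was Scd1 (5912 ± 2674 to 12866 ± 2042 CPM, SD, n = 3), with an adjusted p of 0.123 in edgeR, and 0.00733 to 0.327 over the alternatives. Fasn (-0.59 ± 0.32, SE) and Thrsp (-0.17 ± 0.24) were negative, and Mid1ip1 is not in the panel. None of the 10 panel genes passed the threshold in edgeR, 1 passed unadjusted, and DESeq2 called 1, Scd1. Feeding state stays open, since the panel's median per library ran from -0.49 to 0.64 among the controls. Time of day could also differ. Clock genes grouped as lights-on exceeded those grouped as lights-off by 0.844 in median log2 fold change, between the bounds of 0.3 and 1 set for this test. Past the threshold were Cry1 and Nfil3 of the lights-on group and only Nr1d1 of 8 in the lights-off group. In the latter Per1, Nr1d2, Per3 and Tef lay between -0.11 and 0.04. The grouping by peak hour is coarse and was not checked in these libraries. The labels used here give neither the feeding state nor the hour of collection. Genotype (loss of Selenoo together with Cre), feeding and time of day therefore cannot be told apart for these genes.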
